A study of Mus musculus with 4 samples.

How the data were processed

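Poly A+ RNA from the dissected striatum of mice of the C57BL/6J background, 21 weeks after birth, was sequenced as paired ends from TruSeq libraries. There were 4 libraries, 1 for each of the genotypes HDQ+/+, HDQ150/150, HDQ200/200 and HDQ315/+. The sex of the animals, the number of animals behind each library and whether tissue was pooled are not given in the sources used here. Each library was assigned to its genotype from the genotype stated in the labels, and each value column to its library from the column name.

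The values analysed were 1 table of 29144 features, with an FPKM value and a count value per library. Per the submitters' processing notes, the builds and tools involved were mm10, bcl2fastq 1.8.4, TopHat2 2.0.11, Bowtie2 2.1.0, TopHat, Cufflinks 2.1.1, Cuffdiff and Cuffnorm. The notes give these names with no role or order, and the gene annotation, the strandedness of the counting and the scaling between libraries are not given in the sources used here. The FPKM values, fragments scaled to transcript length and library depth, were used as deposited, per the file headers. The deposited count values were a scaled signal and not raw counts: between 98.1% and 98.4% of the values above 0 in each library lay within 0.05 of a whole multiple of 1 step. The step was 0.781 in HDQ+/+, 1.27 in HDQ150/150, 0.895 in HDQ200/200 and 1.13 in HDQ315/+. Dividing by it gave the whole fragments behind each gene, which are the only source of depth used here. Coordinates are those of the deposited table on mm10, counted from 1.

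Features without a gene name (5934) and short non-coding RNA genes (692) were left out of all tests. The unnamed features held 0.825% of the scaled counts and 45.5% of the FPKM in HDQ+/+, 0.675% and 35.6% in HDQ150/150, 0.829% and 54.7% in HDQ200/200, and 0.739% and 62.3% in HDQ315/+. A gene was tested where its mean FPKM over the 4 libraries was at least 1, which left 12864 genes. Changes are differences of log2(FPKM + 1), a scale that understates the change of genes with low values. A gene was called higher or lower where it differed by at least 1.5-fold on that scale. No p-value was computed, because 1 library per genotype gives no spread between animals; the tests with replicates that had been planned for tables holding them were not used. Ratios of scaled counts carry a 95% interval from the exact Clopper-Pearson method on the fragments of both libraries, which covers counting error only.

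The comparisons were each of the 3 mutant libraries against HDQ+/+, the 3 pairs of mutant libraries, the genes past the fold size in the same direction in all 3 mutants, the genes that rose or fell at each step of the series HDQ+/+, HDQ150/150, HDQ200/200, HDQ315/+ with at least 1.5-fold in total, and the correlation of changes across genes. The ordered genes were counted again for all 12 orders of the 4 libraries, a rising and a falling run of the same order being counted together. All 3 comparisons with HDQ+/+ share its chance values, so 100 simulations with a shared control were run. Their spread per expression class was taken from the differences among the mutants, which hold real differences too, so the simulated gene counts are high. The simulated correlations are instead largely fixed by drawing control and mutants from the same spread.

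For 39 gene lists, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 classes (seed 1). A list was called where its median lay at or under percentile 2.5 or at or over percentile 97.5, and at least 3 members had to be measured. The lists covered neurons of the striatum and of neighbouring regions, glia, vessels, blood, choroid plexus and ependyma, activity and stress programmes, energy metabolism and ribosomes, ion channels and receptors, signalling families, DNA repair, huntingtin interactors, neighbours of Htt and sex-linked genes. Lists could share members. Pde1b and Pde10a (phosphodiesterases), Rgs9 (RGS), Kcnip2 (potassium channels) and Cnr1, Pdyn and Penk (opioid and cannabinoid) were also in projection neuron lists. Kcne2 was in the potassium channel and choroid plexus lists. The metabotropic glutamate receptor list also held Homer2 and Homer3, which do not encode receptors. The complex I list was taken by the name prefixes Ndufa, Ndufb, Ndufc, Ndufs and Ndufv, so its members need not all be subunits. The list of Hox and other developmental regulators had 2 of 58 members measured, Pax6 and Shox2, and so had no list result. Another list, of 28 liver genes, was written after some of them had been seen among the highest genes of HDQ315/+.

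The groups, comparisons, gene lists, fold size and the rule for genes named in the text were fixed before the data were examined. That rule took Htt, the 6 highest and 6 lowest genes of each mutant against HDQ+/+, and the 10 genes higher and 10 genes lower in all 3 mutants with the largest smallest change. It also took the 5 highest and 5 lowest of each mutant pair, and the 5 ordered genes with the largest total change in each direction. From each list it took up to 4 members with the largest mean change, every member of lists of up to 12 genes, and every member of the projection neuron and sex-linked lists. Genes named outside it are said to be chosen afterwards, and some genes that the rule takes are not reported here. Genes of the mitochondrial genome fill many of the extreme places: mt-Co1 was listed at 0 in 3 libraries, the merged feature mt-Atp6,mt-Atp8,mt-Co3 was listed at 0 in HDQ+/+ and HDQ315/+, and the extreme tRNA genes had at most 12 fragments. No fold is given for these or for AF357399, whose value rested on 2 fragments in 1 library.

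Transcript length and GC content came from the longest basic transcript of each symbol in GENCODE M21 and were found for 12738 of the 12864 genes (99.0%). To correct for either, a running median over 501 genes ordered by that property was subtracted from the log2 ratios. The alternatives set at the same time were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 10, a fold of at least 2, median centring, scaling to the upper quartile, short non-coding RNA kept, unmatched random lists, and leaving out each mutant in turn. Alternatives chosen after seeing the data were the scaled counts, the corrections for length and for GC content, unnamed features kept, genes of the mitochondrial genome and genes under 10 scaled counts left out, and markers of choroid plexus, ependyma, cortex, thalamus and liver left out.

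The procedure was tested on simulated data with counting noise alone, for 12843 genes. Genes raised 4-fold or lowered 4-fold were all called in each of the 3 comparisons. Of genes raised 2-fold, 94.1% were called for HDQ150/150, 88.2% for HDQ200/200 and 100% for HDQ315/+, and of genes lowered 2-fold 87.9%, 81.8% and 97.0%. Genes changed by exactly 1.5-fold were called in 9.09% to 29.4% of cases, because the pseudocount shrinks their ratio below the fold size. Of 12643 unchanged genes, 6 were called for HDQ150/150, 4 for HDQ200/200 and 6 for HDQ315/+. A list of 28 genes at 0.5 times lay at percentile 0 in each comparison, and a list of 28 unchanged genes at percentiles 84.5, 77.5 and 6.47. A length trend with a rank correlation of 0.799 was reduced to 0.00653. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.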

Results

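Striatal poly A+ RNA of C57BL/6J mice aged 21 weeks was sequenced from a Huntington's disease knock-in series. There was 1 library for each of 4 genotypes: HDQ+/+, the wild type; HDQ150/150 and HDQ200/200, with mutant alleles on both chromosomes; and HDQ315/+, with 1 mutant and 1 wild-type allele. The libraries held 36877700 (HDQ+/+), 25058800 (HDQ150/150), 33468900 (HDQ200/200) and 26324800 (HDQ315/+) fragments, to 6 digits, assigned to the 29144 features of the table, and 12864 named genes had a mean FPKM of at least 1. Transcripts of the mitochondrial genome made up 7.53%, 15.4%, 9.10% and 11.3% of the counts in the same order, shares that are not comparable between libraries because mt-Co1 and the merged feature mt-Atp6,mt-Atp8,mt-Co3 were listed at 0 in some of them. With no replicate libraries there is no replicate check and no p-value, percentiles of gene lists describe these libraries only, and intervals cover counting error only. All changes below are log2 ratios of FPKM + 1, a gene being called higher or lower from 1.5-fold.

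Htt, the gene that carries the repeat (chromosome 5, 34761740 to 34912521), stood at 7.56 FPKM in HDQ+/+, 4.42 in HDQ150/150, 7.68 in HDQ200/200 and 4.78 in HDQ315/+, from 4120, 1578, 3722 and 1808 fragments. Its log2 ratios to HDQ+/+ were −0.66, 0.02 and −0.57, so that only HDQ150/150 passed the fold size, HDQ315/+ also passing with a pseudocount of 0.1 (−0.65), median centring (−0.61), the upper quartile (−0.63) or GC correction (−0.63). On scaled counts the ratios were 0.623 (95% interval 0.588 to 0.661), 1.04 (0.990 to 1.08) and 0.635 (0.600 to 0.671). After correction for transcript length Htt lay at −0.53, −0.49 and −0.36, all negative and all under the fold size. Between mutants Htt was higher in HDQ200/200 than in HDQ150/150 (0.68), level between HDQ315/+ and HDQ150/150 (0.09), and lower in HDQ315/+ than in HDQ200/200 (−0.59), while the length-corrected values of the 3 mutants differed by less than the fold size. The list of 15 measured genes around Htt on chromosome 5, Htt included, had medians of −0.09, −0.10 and −0.03 (percentiles 15.2, 29.5 and 24.1), the HDQ200/200 value turning to 0.04 on scaled counts and 0.07 after GC correction. Among them Adra2c fell in HDQ200/200 (−1.001) and Zfyve28 fell in the same library (−0.80).

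In HDQ150/150, genes of the striatal projection neurons, the principal output cells of the striatum, were lower than in HDQ+/+. Penk, which encodes the enkephalin precursor (chromosome 4, 4133536 to 4139032), fell from 1029.5 to 305 FPKM (−1.75), Drd1a, the D1 dopamine receptor gene (chromosome 13, 54050851 to 54055658), from 85.9 to 32.7 FPKM (−1.37), and the phosphodiesterase gene Pde10a from 157 to 51.4 FPKM (−1.59). Cortical glutamatergic neuron genes were higher, among them the vesicular glutamate transporter gene Slc17a7 (chromosome 7, 45163921 to 45176139; 57.0 to 199 FPKM, 1.79), as was the synaptic zinc transporter gene Slc30a3 outside that list (4.99 to 22.2 FPKM, 1.95). Choroid plexus genes fell most, with Ttr, the transthyretin gene (chromosome 18, 20665250 to 20674326), going from 1519.9 to 63.9 FPKM (−4.55). In all, 385 genes were higher and 430 lower, 47.2% of the called genes being higher, against 699 and 598 on scaled counts (53.9%).

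Of 28 genes shared by projection neurons, 21 fell in HDQ150/150 and none rose (median −0.99, percentile 0). Among them were Ryr1 (−1.90), the sodium channel subunit gene Scn4b (−1.70), the cannabinoid receptor gene Cnr1 (−1.48) and Ppp1r1b, which encodes DARPP-32 (chromosome 11, 98348738 to 98358283; 829.8 to 425 FPKM, −0.96). Of 9 direct pathway genes 5 fell and 4 were under the fold size (median −0.62, percentile 0), Pdyn going from 41.9 to 17.9 FPKM (−1.19). Of 7 indirect pathway genes 5 fell (median −0.98, percentile 0), including Adora2a (139 to 57.65 FPKM, −1.26) and the D2 receptor gene Drd2 (chromosome 9, 49340662 to 49427021; 85.5 to 42.9 FPKM, −0.98). The 14 striatal interneuron genes were lower by median only (−0.19, percentile 1.09), 2 being higher and 2 lower, and the direction turned to 0.40 with a mean FPKM of at least 10. All 11 cortical genes rose (median 1.27, percentile 100), among them Neurod2 (1.79) and Tbr1 (1.38).

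All 8 measured choroid plexus genes fell in HDQ150/150 (median −2.38, percentile 0), with Kl at −2.95 and Folr1 at −2.49, and 7 of 8 ependymal genes fell (median −0.88, percentile 0). Among families of signalling genes, 4 of 17 phosphodiesterases fell and 1 rose (median −0.30, percentile 0.01), Pde7b at −1.47 against Pde1a at 1.03. This list shares Pde10a and Pde1b with the projection neuron genes. Of the 9 genes of the metabotropic glutamate receptor list, Homer2 and Homer3 included, 2 fell and 1 rose (median −0.30, percentile 0.32), Grm5 at −0.81 against Grm2 at 1.33. Potassium channels lay slightly higher, 13 of 69 rising and 6 falling (median 0.14, percentile 100), a call that ended on scaled counts (0.11) and with a mean FPKM of at least 10 (0.01). The 35 genes of respiratory complexes III to V had a higher median with no gene past the fold size (0.19, percentile 99.1; call ended after length correction, 0.11), while complex I (0.11, percentile 90.2) and the cytosolic ribosomal list (0.09, percentile 74.2) were not called. Outside the lists, Enpp2 fell from 271 to 81.4 FPKM (−1.72) and 1500015O10Rik from 23.7 to 2.69 FPKM (−2.74). Correction for transcript length kept 346 of the 385 higher and 359 of the 430 lower calls.

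**Figure D1:**
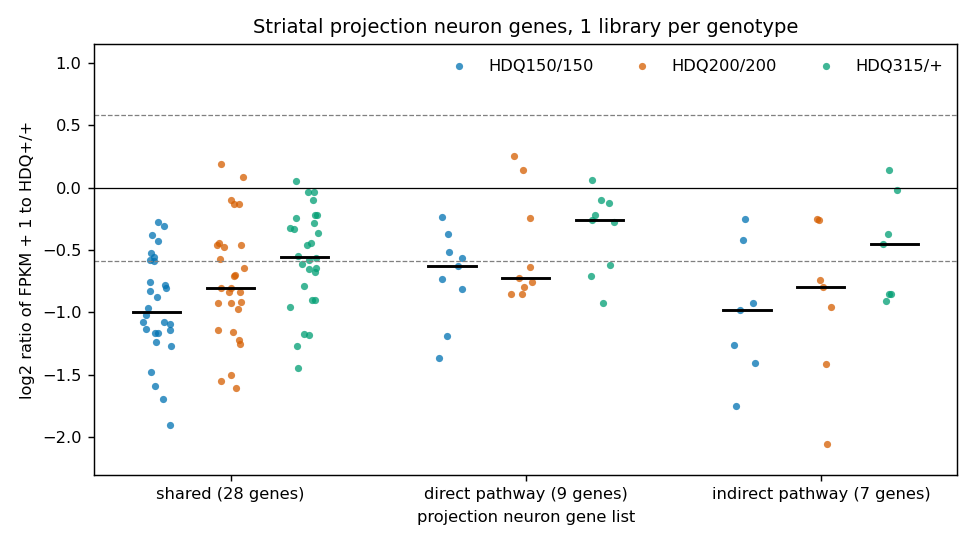
Log2 ratio of FPKM + 1 to HDQ+/+ (vertical axis) of each projection neuron gene, 1 point per gene, by list and mutant library, with medians as black bars and 1.5-fold as dashed lines. Every median lies under 0, the shared list at −0.99, −0.80 and −0.56.

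In HDQ200/200 the projection neuron lists were again lower by median, with Penk going from 1029.5 to 247 FPKM (−2.06), Ppp1r1b from 829.8 to 293 FPKM (−1.50) and Adora2a from 139 to 51.7 FPKM (−1.41). Choroid plexus genes were lower again, Ttr falling from 1519.9 to 49.2 FPKM (−4.92). Haemoglobin genes and immediate early genes were lower in this library, as were most cytosolic ribosomal protein genes. Among the highest genes were the kinase gene Hipk2 (1.91 to 11.8 FPKM, 2.14), Cdr1 (9.81 to 34.45 FPKM, 1.71), Tmem245 (1.14 to 6.05 FPKM, 1.72) and the potassium channel gene Kcnh7 (0.918 to 4.97 FPKM, 1.64). In all, 692 genes were higher and 1132 lower (37.9% higher), against 903 and 904 after median centring, 999 and 835 with the upper quartile, 1287 and 1038 on scaled counts and 718 and 719 after GC correction.

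Of the 28 shared projection neuron genes 18 fell in HDQ200/200 (median −0.80, percentile 0), Rasgrp2 (−1.60), Ryr1 (−1.55) and Rgs9 (−1.22) among them, while Strn (0.19) and Dgkb (−0.13) did not pass the fold size. Of 9 direct pathway genes 6 fell (median −0.73, percentile 0.01), Tac1 going from 286 to 164 FPKM (−0.80) and Drd1a from 85.9 to 51.5 FPKM (−0.73). Of 7 indirect pathway genes 5 fell (median −0.80, percentile 0), with Drd2 at −0.74. Cortical genes were higher in 9 of 11 cases (median 0.81, percentile 100), Neurod6 at 0.99 and Neurod2 at 0.89. All 8 choroid plexus genes fell (median −2.50, percentile 0) and 7 of 8 ependymal genes did (median −0.79, percentile 0; −0.36 after length correction). Of 3 measured hypothalamic neuropeptide genes only Pomc fell (−1.18), with a median of −0.52 (percentile 1.69; call ended after length correction, −0.14).

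All 3 members of the haemoglobin list fell in HDQ200/200 (median −1.95, percentile 0), the merged feature Hba-a1,Hba-a2, whose near-identical copies share reads, going from 70.0 to 16.8 FPKM (−2.00) and the haem synthesis gene Alas2 from 3.86 to 0.887 FPKM (−1.36). Of 21 immediate early genes 10 fell and none rose (median −0.52, percentile 0), Junb going from 73.0 to 29.0 FPKM (−1.30) and Egr2 from 11.5 to 3.61 FPKM (−1.44). Of the 96 members of the cytosolic ribosomal list 70 fell (median −0.69, percentile 0), Rps29 at −1.07 and Rpl31 at −0.99; 84 of the 96 carry the name of a subunit or its pseudogene, 67 of these falling, and 12 share only the name prefix. Genes of the complex I list, taken by name prefix and not all necessarily subunits, fell in 24 of 45 cases (median −0.61, percentile 0.01), Ndufa1 at −1.01. Genes of complexes III to V fell in 19 of 35 (median −0.60, percentile 0.79), Atp5l at −0.81. After length correction these medians were −0.23, −0.14 and −0.13, and the calls of both complex lists ended.

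Several families of channels, receptors and adhesion genes had higher medians in HDQ200/200. GABA receptor and synthesis genes rose in 4 of 17 cases and fell in 1 (median 0.34, percentile 100; 0.21 after length correction), Gabbr2 at 0.78 against Gabrd at −1.02. Potassium channels rose in 11 of 69 cases and fell in 7 (median 0.28, percentile 100; 0.11 after length correction). Beta protocadherins, 17 genes of 1 locus, had 2 members past the fold size, both higher (median 0.40, percentile 100). Of 15 ionotropic glutamate receptors 4 rose (median 0.18, percentile 98.4), a direction that turned to −0.01 after length correction. Of 5 sex-linked transcripts 3 rose (median 0.60, percentile 99.8; call ended after length correction, 0.28, and GC correction, 0.34), Xist going from 24.3 to 48.7 FPKM (0.98) and the Y-linked Ddx3y from 7.43 to 11.8 FPKM (0.60). Length correction kept 228 of the 692 higher and 341 of the 1132 lower calls.

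In HDQ315/+, thalamic neuron genes were higher, with the kinase gene Prkcd (chromosome 14, 30595354 to 30626255) going from 3.36 to 35.5 FPKM (3.06), the transcription factor gene Tcf7l2 from 3.48 to 22.4 FPKM (2.38) and the glutamate transporter gene Slc17a6 from 1.30 to 14.8 FPKM (2.78). Projection neuron genes were lower, Penk falling from 1029.5 to 569.9 FPKM (−0.85) and Cnr1 from 82.7 to 29.8 FPKM (−1.44), and so was the choroid plexus gene Ttr, from 1519.9 to 305 FPKM (−2.31). Among the highest genes of the comparison were Alb, the albumin gene, from 0.132 to 77.0 FPKM (6.11), and the apolipoprotein gene Apoa2, from 0.647 to 39.4 FPKM (4.61). Both belong to the list of liver genes, which stood out in this library alone. The source of these transcripts was not tested. In all, 375 genes were higher and 274 lower (57.8% higher). The counts were 294 and 355 after median centring, 263 and 390 with the upper quartile, 614 and 702 on scaled counts, and 242 and 283 after length correction.

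Of the 28 shared projection neuron genes 12 fell in HDQ315/+ (median −0.56, percentile 0), Scn4b at −1.27, Ryr1 at −1.18 and Pde10a at −1.17, while Ppp1r1b (−0.46) and Rasgrp2 (−0.28) stayed under the fold size. Of 9 direct pathway genes 3 fell (median −0.26, percentile 0.35), Drd1a at −0.93 but Tac1 at 0.06. Of 7 indirect pathway genes 3 fell (median −0.45, percentile 0.01), Gpr52 at −0.91 and Adora2a at −0.85, with Drd2 under the fold size (−0.45). Thalamic genes rose in 7 of 8 cases (median 1.64, percentile 100), against medians of −0.10 in HDQ150/150 and −0.00 in HDQ200/200 (percentiles 19 and 42), the last turning to 0.13 on scaled counts. Gbx2 (0.576 to 4.605 FPKM, 1.83) and Zic1 (5.68 to 16.8 FPKM, 1.42) were among the 7, and Shox2, a developmental regulator measured outside that list, rose from 0.449 to 10.1 FPKM (2.94). Cortical genes were mixed, 4 of 11 rising and 2 falling (median 0.33, percentile 99.8, or 91.6 with a mean FPKM of at least 10), Neurod6 at 1.40 against Tbr1 at −0.62. Striatal interneuron genes had a median of −0.24 (percentile 0.11) and a mean of 0.04, the signs differing, with Calb2 at 2.55 and a median of 0.34 where the mean FPKM was at least 10.

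All 8 choroid plexus genes fell in HDQ315/+ (median −1.75, percentile 0), whereas 2 of 8 ependymal genes rose and none fell (median 0.16, percentile 92.9; −0.14 after length correction). Immediate early genes fell in 13 of 21 cases (median −0.69, percentile 0), Egr2 at −1.75 and Nr4a1 at −1.52, and all 3 members of the haemoglobin list fell (median −1.46, percentile 0). Oligodendrocyte genes had 2 of 18 members lower (median −0.09, percentile 0.64; uncalled on scaled counts and against unmatched lists, at percentiles 4.15 and 4.75), including the myelin gene Mobp (−0.69). Endothelial and mural genes had 1 of 15 lower (median −0.22, percentile 0.16; −0.09 and uncalled with a mean FPKM of at least 10), and none of 21 cholesterol synthesis genes passed the fold size (median −0.17, percentile 0.34; −0.10 and uncalled after GC correction). Complex I genes rose in 3 of 45 cases (median 0.35, percentile 100), the ribosomal list had 5 of 96 members rising, 1 of them the pseudogene Rps15a-ps6, chosen afterwards, and 1 falling, which is not a subunit (median 0.35, percentile 100), and complexes III to V had a median of 0.39 (percentile 100). After length correction these medians were 0.07, 0.07 and 0.11 and all 3 calls ended (percentiles 82.9, 91.5 and 93.6).

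Several signalling families had lower medians in HDQ315/+ with few members past the fold size, and each of the 6 named next lost its call after length correction. Some of them share members with the projection neuron lists. Phosphodiesterases fell in 3 of 17 cases (median −0.22, percentile 0.12) and potassium channels fell in 4 of 69 and rose in 3 (median −0.10, percentile 0.05). GABA receptor and synthesis genes had 1 of 17 higher, Gabra5 (1.04), and a median of −0.14 (percentile 0.36). RGS genes, regulators of G protein signalling, had a median of −0.18 (percentile 0.16) and a mean of 0.03, the signs differing: Rgs4 fell (−0.86) and Rgs16 rose (2.08). The metabotropic glutamate receptor list, Homer2 and Homer3 included, also differed in sign between median (−0.21, percentile 1.72) and mean (0.04). Of its 9 members 2 rose, among them Grm2 (1.08). Opioid and cannabinoid genes rose in 2 and fell in 3 of 10 cases (median −0.23, percentile 0.5), Pnoc at 1.24 against Penk at −0.85. Of 5 sex-linked transcripts 2 fell (median −0.36, percentile 0.6; call ended after GC correction, −0.27), Xist at −0.82 and Ddx3y at −0.76. Length correction kept 198 of the 375 higher and 193 of the 274 lower calls.

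**Figure D2:**
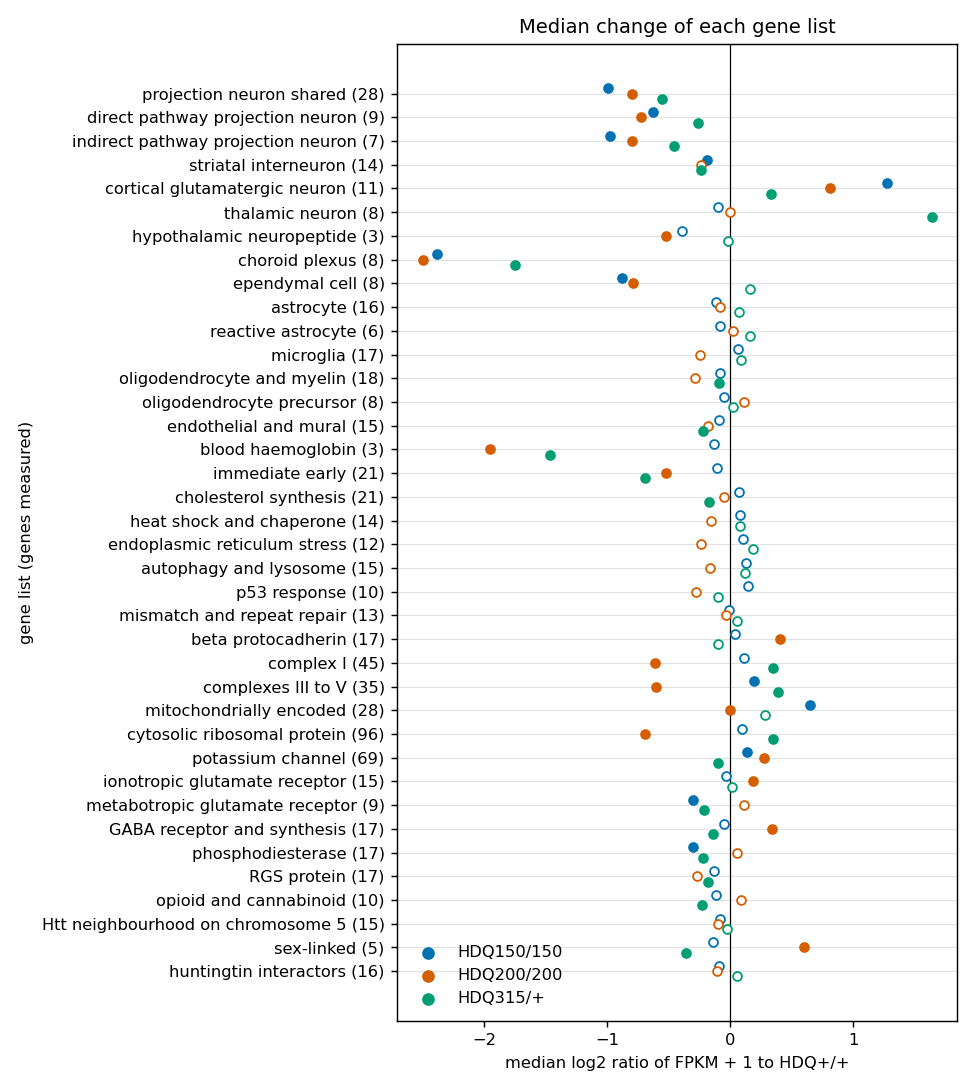
Median log2 ratio of FPKM + 1 to HDQ+/+ (horizontal axis) of each gene list other than liver, 1 point per mutant library, filled where the list was called against matched random lists and open otherwise. The choroid plexus lies furthest to the left (−2.38, −2.50 and −1.75) and the thalamic list in HDQ315/+ furthest to the right (1.64).

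Some programmes were called in none of the 3 mutants. Astrocyte genes had medians of −0.12, −0.08 and 0.07, the HDQ200/200 value turning to 0.01 after length correction, and reactive astrocyte genes −0.08, 0.02 and 0.16, with Serpina3n alone past the fold size (2.59 to 7.68 FPKM, 1.27 in HDQ315/+). Microglia genes had 0.06, −0.25 and 0.09, the HDQ315/+ value turning to −0.11 after length correction. Oligodendrocyte precursor genes had −0.05, 0.11 and 0.03, Gpr17 being higher in HDQ200/200 (0.62), and the HDQ150/150 and HDQ200/200 values changed sign after length correction, the HDQ315/+ value with median centring and scaled counts. Heat shock and chaperone genes had 0.08, −0.15 and 0.08, the HDQ200/200 value turning to 0.03 after length correction, endoplasmic reticulum stress genes 0.11, −0.24 and 0.18 and autophagy and lysosome genes 0.13, −0.17 and 0.12. The p53 response had 0.14, −0.28 and −0.10, Bax (−0.73) and Gadd45b (−0.70) falling in HDQ200/200, where the median turned to 0.03 after length correction and 0.00 after GC correction. Mismatch and repeat repair genes had −0.01, −0.04 and 0.06, the HDQ200/200 and HDQ315/+ values changing sign on scaled counts and after length correction. The 16 huntingtin interactors had −0.09, −0.11 and 0.06, the HDQ200/200 value turning to 0.23 on scaled counts and 0.11 after GC correction and the HDQ315/+ value turning to −0.01 under both.

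Lists called in some mutants were uncalled in the others. Uncalled medians in HDQ150/150 were −0.39 for hypothalamic neuropeptides, −0.08 for oligodendrocytes, −0.09 for endothelial and mural cells, −0.13 for haemoglobin and −0.11 for immediate early genes. They were 0.07 there for cholesterol synthesis, 0.04 for beta protocadherins, −0.04 for ionotropic glutamate receptors, −0.13 for RGS genes, −0.11 for opioid and cannabinoid genes and −0.14 for sex-linked transcripts. GABA receptor and synthesis genes stood at −0.05 in HDQ150/150, turning above 0 after length and GC correction. In HDQ200/200 the uncalled medians were −0.24 for striatal interneurons, −0.28 for oligodendrocytes, −0.18 for endothelial and mural cells, −0.05 for cholesterol synthesis (above 0 with median centring and length correction), 0.11 for metabotropic glutamate receptors and −0.27 for RGS genes. Phosphodiesterases stood at 0.05 in HDQ200/200, turning to −0.15 after length correction and −0.11 after GC correction. Opioid and cannabinoid genes there had a median of 0.09 and a mean of −0.22, the signs differing. In HDQ315/+ the uncalled medians were −0.02 for hypothalamic neuropeptides, −0.10 for beta protocadherins and 0.02 for ionotropic glutamate receptors, the last turning below 0 with median centring and GC correction. Mitochondrially encoded genes had medians of 0.65, 0.00 and 0.29, which are unreliable because several features were listed at 0 and the tRNA genes rested on few fragments.

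Across all 3 mutants, 26 genes were higher and 76 lower than in HDQ+/+. The higher genes included Slc17a6 and the cortical transcription factor genes Neurod1, Neurod2, Neurod6 and Bhlhe22. The mitochondrial gene mt-Nd5 (3024, 5561, 5736 and 5266 FPKM) was higher too, but values of that genome are unreliable because several of its features were listed at 0. Outside the lists, Prdm8 (1.71, 1.21 and 1.54 in HDQ150/150, HDQ200/200 and HDQ315/+), Fam19a1 (1.58, 0.82 and 1.06), C1ql3 (1.27, 0.90 and 0.82), Gpr123 (1.10, 0.83 and 0.80) and Ptpn3 (0.91, 0.75 and 1.37) rose. The lower genes included Adcy5 (−1.14, −0.64 and −0.90), Arpp21 (−1.14, −0.93 and −0.68), Pde1b (−1.02, −0.91 and −0.64), Cnr1, Ryr1 and Scn4b of the shared projection neuron list. Chrm4 (−0.81, −0.86 and −0.62), Drd1a and Pdyn of the direct pathway and Adora2a, Gpr52 and Penk of the indirect pathway fell in each mutant. Chrm4 was under the fold size in HDQ200/200 after length correction (−0.50). The choroid plexus gave the largest falls, with Ttr (−4.55, −4.92 and −2.31), Kl (−2.95, −2.55 and −2.16), Kcne2, Folr1, Sostdc1 and, outside the list, Kcnj13 (−2.32, −2.13 and −1.80) and Enpp2 (−1.72, −1.49 and −1.51). Egr2 (−1.28, −1.44 and −1.75), Pomc (−0.78, −1.18 and −0.62), Rgs4 (−0.93, −0.93 and −0.86) and Pde7b (−1.47, −0.67 and −0.91) also fell in all 3.

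If the 3 comparisons were independent, 0.604 higher and 0.806 lower genes would have passed in all 3, but they share 1 control library. Simulations with a shared control gave 217 higher genes (187 to 251) and 216 lower (171 to 254), values that are high because their spread was taken from the differences among the mutants. After length correction 38 genes were higher and 92 lower in all 3, against 107 (82 to 127) and 118 (95 to 141) simulated, and 22 of the 26 and 65 of the 76 kept their call. Calls shared by HDQ150/150 and HDQ200/200 numbered 98 higher and 232 lower, by HDQ150/150 and HDQ315/+ 103 and 152, and by HDQ200/200 and HDQ315/+ 31 and 97. The changes of HDQ150/150 correlated with those of HDQ200/200 at r = 0.331 and with those of HDQ315/+ at r = 0.446. HDQ200/200 and HDQ315/+ had r = −0.0516, turning to 0.00606 after GC correction. Length correction moved the 3 values to 0.475, 0.429 and 0.173 in that order, so that the first became the largest. The shared-control simulations gave 0.499 to 0.502, higher than the observed r in each pair. Drawing control and mutants from the same spread largely fixes the simulated r and rank values, so setting the observed values against them does not test for shared change. By rank, HDQ150/150 and HDQ315/+ lay above their simulation (0.614), and the other pairs far below (0.146 for HDQ150/150 with HDQ200/200, −0.262 for HDQ200/200 with HDQ315/+), each simulated at 0.478. The rank values were not corrected for transcript length, which HDQ200/200 followed in the opposite direction to HDQ150/150 and HDQ315/+, so they include that trend. Without the mitochondrial genome r was 0.298, 0.540 and −0.118 in the order given above.

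Along the series HDQ+/+, HDQ150/150, HDQ200/200, HDQ315/+, 26 genes rose and 9 fell at every step with at least 1.5-fold in total. The falling genes included Egr2 (11.5, 4.18, 3.61 and 2.72 FPKM), Nr4a1 (58.4, 40.2, 32.3 and 19.7 FPKM) and Btg2 (7.135, 6.21, 3.82 and 2.90 FPKM), which are induced by neuronal activity or growth signals, and Ddit4l (10.99, 5.23, 5.17 and 4.79 FPKM) and Abi3bp (3.45, 3.44, 2.28 and 1.16 FPKM). The rising genes changed mostly in HDQ315/+. They included Tcf7l2 of the thalamic list (3.48, 3.55, 3.82 and 22.4 FPKM), Abhd12b (0.191, 0.204, 0.3201 and 6.52 FPKM), Inadl (1.66, 1.92, 2.02 and 6.57 FPKM) and Shisa6 (0.799, 1.12, 1.57 and 3.44 FPKM). Also among them was the liver gene Cyp2e1 (0.184, 0.389, 0.601 and 8.39 FPKM), of the liver list whose members stood out in HDQ315/+. Counted over all 12 orders of the 4 libraries, this order gave 35 genes and ranked 11, the range being 34 to 2061 and the median 167. The order HDQ200/200, HDQ+/+, HDQ150/150, HDQ315/+ gave the most, with 1237 genes rising and 824 falling. The orders were counted without correction for transcript length. Rank correlations of change with length were 0.609 in HDQ200/200, −0.234 in HDQ150/150 and −0.490 in HDQ315/+, which gives the same order, so the ranking includes that trend. Falling genes of the series numbered 23 after length correction, 21 after GC correction and 22 on scaled counts. Series position and number of mutant alleles cannot be separated, because HDQ315/+, the last of the series, carries 1 mutant allele and HDQ150/150 and HDQ200/200 carry 2.

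Against HDQ150/150, HDQ200/200 had 980 genes higher and 1386 lower (41.4% higher). The ribosomal list, 12 of its 96 members not being named for subunits, was lower in 79 members and higher in 2 (median −0.81, percentile 0), complex I genes lower in 32 of 45 (−0.78, percentile 0) and genes of complexes III to V in 28 of 35 (−0.82, percentile 0.01). After length correction these medians were −0.25, −0.18 and −0.18, and the calls of both complex lists ended. The haemoglobin list was lower in all 3 members (median −1.87, percentile 0), or −0.95 after length correction over the members with a length. Microglia genes were lower in 6 of 17 cases (−0.47, percentile 0.27, or −0.08 after length correction) and cortical genes in 4 of 11 (−0.45, percentile 0.13), Slc17a7 at −0.90. Shared projection neuron genes were higher in 7 of 28 cases and lower in 2 (median 0.24, percentile 100; 0.11 after length correction), Strn at 1.35 and Pde10a at 1.12. The choroid plexus list was level (median 0.03) before length correction and at 0.26 after it. The counts were 1213 and 1107 after median centring, 1367 and 949 with the upper quartile and 430 and 394 after length correction.

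HDQ315/+ and HDQ150/150 were the closest pair, with 325 genes higher and 254 lower in HDQ315/+ (56.1% higher). Thalamic genes were higher in 7 of 8 cases (median 1.83, percentile 100) and ependymal genes in 7 of 8 (1.08, percentile 100), while choroid plexus genes were higher in 6 of 8 (0.73, percentile 100), Ttr at 2.24. Cortical genes were lower in 7 of 11 cases (median −0.88, percentile 0), Slc17a7 at −1.46. Shared projection neuron genes were higher in 4 of 28 cases and lower in none (median 0.38, percentile 100; 0.37 after length correction). Direct pathway genes had a higher median with none past the fold size (0.44, percentile 100), and the indirect pathway median was 0.52 (percentile 100), Penk at 0.90. Immediate early genes were lower in 7 of 21 cases (median −0.43, percentile 0) and the haemoglobin list in all 3 members (−1.36, percentile 0). The counts were 258 and 302 with the upper quartile, 420 and 494 on scaled counts, and 230 and 301 after length correction.

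HDQ315/+ and HDQ200/200 were the most distant pair, with 2346 genes higher and 1411 lower in HDQ315/+ (62.4% higher). The ribosomal list was higher in 82 of 96 members and lower in 2 (median 1.08, percentile 100), complex I genes in 37 of 45 (0.94, percentile 100) and genes of complexes III to V in 32 of 35 (0.99, percentile 100). After length correction these medians were 0.28, 0.21 and 0.17, and the calls of both complex lists ended. Thalamic genes were higher in 7 of 8 cases (median 1.88, percentile 100), ependymal genes in 7 of 8 (1.06, or 0.22 after length correction) and microglia genes in 6 of 17 (0.44, percentile 94.6, turning to −0.15 after length correction). Potassium channels were lower in 20 of 69 cases (median −0.16, percentile 0.14; −0.06 after length correction), and Rims1, a presynaptic gene, was lower (−2.78), with 5.64, 5.85, 17.9 and 1.745 FPKM in the 4 libraries. Shared projection neuron genes were higher in 10 and lower in 4 of 28 cases (median 0.26, percentile 4.51), Penk at 1.20 and Strn at −1.08. The counts were 1750 and 1897 after median centring, 1547 and 2078 with the upper quartile, 2328 and 2355 on scaled counts, 712 and 732 after length correction and 1530 and 1451 after GC correction.

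**Figure D3:**
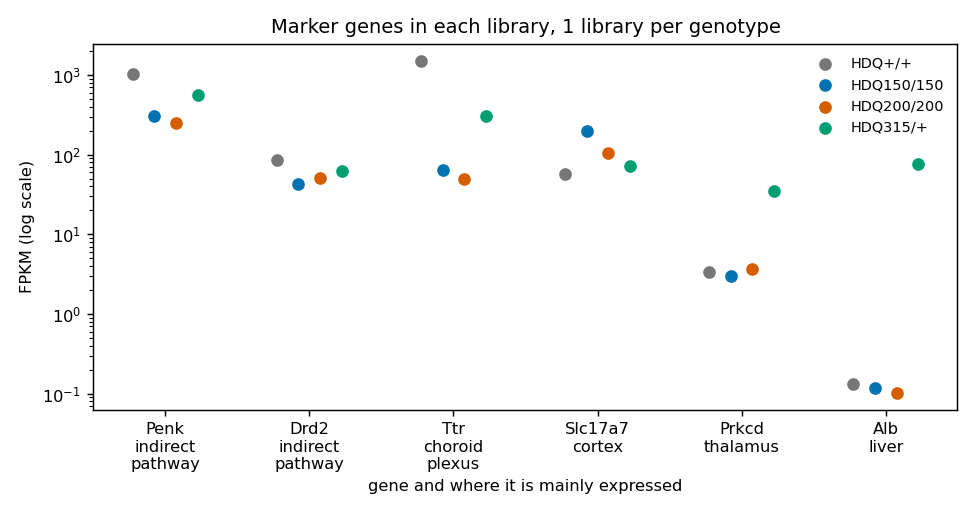
FPKM on a log scale of 6 genes named with the tissue or cell type that mainly expresses them, 1 point per library. Alb stands at 77.0 FPKM in HDQ315/+ and at 0.132 in HDQ+/+, and Ttr at 1519.9 in HDQ+/+.

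The change of a gene followed its transcript length in every mutant, HDQ200/200 in the opposite direction to the other 2. The rank correlation with length was −0.234 in HDQ150/150, 0.609 in HDQ200/200 and −0.490 in HDQ315/+. In 10 groups of equal size by length, genes of the shortest transcripts, up to 1266 bases, had medians of 0.10, −0.49 and 0.30, and genes of the longest, from 6791 bases, −0.12, 0.40 and −0.19. Rank correlations with GC content were 0.234, −0.368 and 0.251. Projection neuron and choroid plexus genes kept their direction after length correction, the shared projection neuron list at −0.997, −0.81 and −0.51 and the choroid plexus list at −2.45, −2.17 and −1.96.

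**Figure D4:**
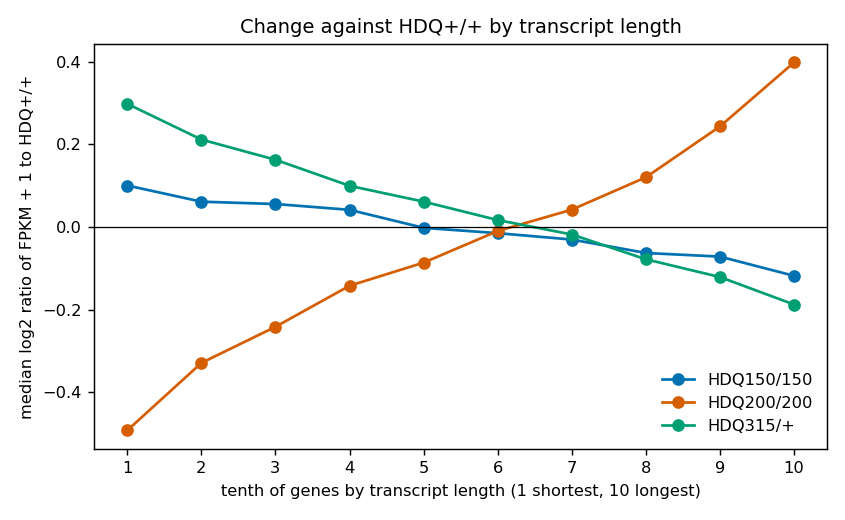
Median log2 ratio of FPKM + 1 to HDQ+/+ in 10 groups of genes from the shortest to the longest transcripts, 1 line per mutant library. The HDQ200/200 line climbs from −0.49 to 0.40 and the HDQ315/+ line descends from 0.30 to −0.19.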

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

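In this part the GC tests were set before their result was seen; the tests against transcript length were chosen after it. The length test was also altered after its result was seen. It first matched random lists on transcript length alone, then also on a mean FPKM of at least 10, and last asked in addition for the percentile after length correction.

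Genes of short transcripts moved in opposite directions between mutants, which marked them for a closer look; the differences between mutants were not tested, with 1 library each. Complex I had a median log2 ratio of −0.61 in HDQ200/200 and 0.35 in HDQ315/+. Complexes III to V stood at −0.60 in HDQ200/200, 0.19 in HDQ150/150 and 0.39 in HDQ315/+, and the list of cytosolic ribosomal protein genes, 84 of its 96 members being named for subunits, at −0.69 in HDQ200/200 and 0.35 in HDQ315/+.

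For HDQ200/200, a trend with GC content as the whole source was argued against for both groups: after GC correction the median was −0.51 over both complex lists (percentile 0) and −0.61 for ribosomal protein genes (percentile 0). Ribosomal protein genes lay at percentile 0 of lists matched on length (any level) and percentile 0 with the limit on level, −0.72 against −0.47 (−0.54 to −0.41). Length correction left them at −0.23 and percentile 0.03. These values argue against a trend with the lengths used, those of the longest basic transcripts (median 940 bases at any level). The lengths of the transcripts expressed were not measured, so a length trend is not excluded. For the complexes the matched lists gave percentile 0 at any level and 0.04 with the limit, −0.61 against −0.47 (−0.55 to −0.41), but length correction left −0.14 for complex I and −0.13 for complexes III to V, at percentiles 23.9 and 57.4. A length trend and a change of the complexes therefore cannot be told apart, because the matched and the corrected values disagree; before the last alteration of the test the matched values alone had counted against length, so that alteration turned the verdict. For ribosomal protein genes an effect of the genotype remains open and untested. So do a trend with the length of the transcripts expressed and a difference in RNA quality or library preparation between single libraries.

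Other groups had opposite directions in different mutants, which is what marked them, and these differences were not tested either. Potassium channels had medians of −0.10 in HDQ315/+, 0.14 in HDQ150/150 and 0.28 in HDQ200/200. GABA receptor and synthesis genes had −0.14 in HDQ315/+ and 0.34 in HDQ200/200. Sex-linked transcripts had −0.36 in HDQ315/+ and 0.60 in HDQ200/200. Length correction ended the calls of potassium channels (−0.03) and GABA genes (−0.05) in HDQ315/+. It also ended the call of sex-linked transcripts in HDQ200/200 (0.28).

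Rn45s, a ribosomal RNA precursor left out of all comparisons, was marked because its signal in a feature the report does not use was above the wild-type level. It held 539503 scaled counts in HDQ150/150, against 256647 in HDQ+/+, 230984 in HDQ200/200 and 257385 in HDQ315/+.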

How the results depend on the processing

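Scaled counts, the corrections for transcript length and GC content, unnamed features kept, and the omission of mitochondrial and low genes or of other-tissue markers were chosen after the data had been seen; the other alternatives were set earlier. Over all alternatives, 153 counts and correlations stayed the same and 92 moved. Of list results 884 stayed the same, 37 became stronger, 45 weaker and 3 reversed, and of single genes 5337 stayed the same, 187 became stronger, 209 weaker and 1 reversed. Median centring, short non-coding RNA kept, mitochondrial and low genes left out, and markers of choroid plexus, ependyma, cortex, thalamus and liver left out each kept all 16 counts within 1.5 times. A stricter filter tests fewer genes, and a higher fold or pseudocount lets fewer pass. For all other changes listed here the cause was not tested.

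With a pseudocount of 0.1, HDQ150/150 had 579 genes higher and 673 lower, HDQ200/200 1043 higher and HDQ315/+ 577 higher and 477 lower, and HDQ315/+ against HDQ150/150 512 higher and 387 lower. Genes higher in all 3 mutants numbered 61 and falling genes of the series 21. Correlations were 0.355 (HDQ150/150 with HDQ200/200), 0.410 (HDQ150/150 with HDQ315/+) and −0.0186 (HDQ200/200 with HDQ315/+). The metabotropic glutamate receptor list, Homer2 and Homer3 included, lost its call in HDQ315/+ (−0.22). With a pseudocount of 5, HDQ150/150 had 185 higher and 193 lower, HDQ200/200 201 and 616, HDQ315/+ 147 and 108. The pairs had 353 and 799 (HDQ200/200 against HDQ150/150), 124 and 104 (HDQ315/+ against HDQ150/150) and 1437 and 597 (HDQ315/+ against HDQ200/200), genes shared by all 3 mutants 3 and 39, and rising genes 6. Without a filter 41 genes rose along the series.

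With a mean FPKM of at least 10, HDQ150/150 had 182 higher and 212 lower, HDQ200/200 228 higher, HDQ315/+ 162 and 135, HDQ200/200 against HDQ150/150 382 higher, HDQ315/+ against HDQ150/150 91 and 102, and HDQ315/+ against HDQ200/200 545 lower. Genes shared by all 3 mutants numbered 10 and 29, rising genes 2 and falling genes 3. Striatal interneuron genes reversed to 0.40 in HDQ150/150 and 0.34 in HDQ315/+. Calls ended for cortical genes in HDQ315/+ (0.33, percentile 91.6), endothelial and mural genes in HDQ315/+ (−0.0873), complexes III to V in HDQ200/200 (−0.60, a percentile just over the bound), potassium channels in HDQ150/150 (0.00763) and ionotropic glutamate receptors in HDQ200/200 (0.11). Calls appeared for immediate early genes in HDQ150/150 (−0.24), ionotropic glutamate receptors in HDQ150/150 (−0.21) and HDQ315/+ (−0.18), RGS genes in HDQ150/150 (−0.44) and HDQ200/200 (−0.63), and opioid and cannabinoid genes in HDQ150/150 (−0.54). With a fold of at least 2, the counts higher and lower were 96 and 96 in HDQ150/150, 84 and 140 in HDQ200/200, and 84 and 44 in HDQ315/+. They were 135 and 114 for HDQ200/200 against HDQ150/150, 85 and 74 for HDQ315/+ against HDQ150/150, 520 and 321 for HDQ315/+ against HDQ200/200, 1 and 21 in all 3 mutants, and 9 rising and 5 falling.

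With scaled counts, HDQ150/150 had 699 higher, HDQ200/200 1287 higher, HDQ315/+ 614 and 702, HDQ200/200 against HDQ150/150 1522 higher, HDQ315/+ against HDQ150/150 494 lower and HDQ315/+ against HDQ200/200 2355 lower. Genes higher in all 3 numbered 80, falling genes 22, and correlations were 0.404, 0.403 and −0.0932 in the order above. Calls ended for oligodendrocytes (−0.0614), metabotropic glutamate receptors (−0.18) and opioid and cannabinoid genes (−0.22) in HDQ315/+, mitochondrially encoded genes in HDQ200/200 (−0.29) and potassium channels in HDQ150/150 (0.11), and appeared for oligodendrocytes (−0.0780) and RGS genes (−0.16) in HDQ150/150 and huntingtin interactors in HDQ200/200 (0.23). Setd2, a huntingtin interactor, reversed from −0.61 to 0.45 in HDQ200/200. Upper quartile scaling gave 1547 genes higher in HDQ315/+ than in HDQ200/200.

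After length correction, HDQ200/200 had 428 higher and 490 lower, HDQ315/+ 242 higher, HDQ200/200 against HDQ150/150 430 and 394, and HDQ315/+ against HDQ200/200 712 and 732. Falling genes numbered 23 and correlations were 0.475, 0.429 and 0.173. Calls ended for complex I in HDQ200/200 (−0.14) and HDQ315/+ (0.0685), complexes III to V in HDQ150/150 (0.11), HDQ200/200 (−0.13) and HDQ315/+ (0.11), ribosomal proteins in HDQ315/+ (0.0725), hypothalamic neuropeptides in HDQ200/200 (−0.14) and sex-linked transcripts in HDQ200/200 (0.28). In HDQ315/+ they also ended for potassium channels (−0.0274), metabotropic glutamate receptors (−0.14), GABA genes (−0.0537), phosphodiesterases (−0.11), RGS genes (−0.10) and opioid and cannabinoid genes (−0.13), and appeared for mitochondrially encoded genes (−0.0490) and the p53 response (−0.20). Calls also appeared for hypothalamic neuropeptides (−0.47), oligodendrocytes (−0.13), cholesterol synthesis (0.12) and RGS genes (−0.15) in HDQ150/150, and RGS genes in HDQ200/200 (−0.33), while ionotropic glutamate receptors reversed in HDQ200/200 (−0.0127).

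After GC correction, HDQ200/200 had 719 lower, HDQ200/200 against HDQ150/150 768 lower and HDQ315/+ against HDQ200/200 1530 higher, with 21 falling genes and correlations of 0.392 (HDQ150/150 with HDQ200/200) and 0.00606 (HDQ200/200 with HDQ315/+). Calls appeared in HDQ150/150 for astrocytes (−0.14), oligodendrocytes (−0.11), immediate early genes (−0.17), cholesterol synthesis (0.12) and RGS genes (−0.18). They appeared for microglia in HDQ200/200 (−0.25) and mitochondrially encoded genes in HDQ315/+ (0.35). Calls ended in HDQ200/200 for hypothalamic neuropeptides (−0.34), mitochondrially encoded genes (−0.23) and sex-linked transcripts (0.34), and in HDQ315/+ for cholesterol synthesis (−0.10), metabotropic glutamate receptors (−0.21), GABA genes (−0.0850) and sex-linked transcripts (−0.27). Unnamed features kept gave 16 falling genes.

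Against random lists not matched on expression the medians stay and only percentiles move. Calls ended for hypothalamic neuropeptides (−0.52), mitochondrially encoded genes (0) and ionotropic glutamate receptors (0.18) in HDQ200/200 and oligodendrocytes in HDQ315/+ (−0.0899). They appeared for hypothalamic neuropeptides (−0.39), complex I (0.11) and ribosomal proteins (0.0945) in HDQ150/150, oligodendrocytes in HDQ200/200 (−0.28) and mitochondrially encoded genes in HDQ315/+ (0.29). Genes shared by the mutants numbered 103 higher and 152 lower without HDQ200/200, and 98 and 232 without HDQ315/+.

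No paired analysis was possible because each genotype had 1 library and the columns carry no numbers that link them. Alternatives meant for tables with replicates were not run, namely a replicate block, leaving out a replicate, and edgeR and DESeq2 scaling, and no split of the control library was possible. Depth limits the lowest genes most: the libraries held 25058800 to 36877700 fragments, and genes under a mean FPKM of 1 were not tested.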

Other observations

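Of the tests in this part, that of the low choroid plexus genes was set before its result was seen, though its first verdict, in favour of more tissue, was afterwards changed to undecided; the tests on cholinergic genes and both length corrections were chosen after it.

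Transcripts of genes expressed mainly in liver stood out in HDQ315/+. All 28 genes of a list written after some had been seen were over 5 times their highest value in any other library, by 6.51 to 564 times (median 47.6), the highest of the other libraries being set to at least 3 fragments. They held 158 fragments in HDQ+/+, 88 in HDQ150/150, 102 in HDQ200/200 and 10445 in HDQ315/+. Alb (chromosome 5, 90460889 to 90476603) had 0.132, 0.118, 0.101 and 77.0 FPKM in the order HDQ+/+, HDQ150/150, HDQ200/200, HDQ315/+, Apoa2 had 0.647, 1.10, 0.398 and 39.4 FPKM, and Fabp1 had 19.2 FPKM in HDQ315/+ and was listed at 0 in the others. Mup3 (28.9 FPKM) and Mup20 (23.4) were also high there, but their near-identical copies share reads.

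Every library held both Xist, expressed from an inactive X chromosome, and Y-linked transcripts, which a single XX or XY animal would not. The sex-linked values may therefore depend in part on the animals behind each library, whose number and sex are not given in the sources used here. That was not tested. Xist stood at 24.3, 17.4, 48.7 and 13.3 FPKM and Ddx3y at 7.43, 4.56, 11.8 and 3.98 FPKM, and both were highest in HDQ200/200 and lowest in HDQ315/+. Kdm5d rose in HDQ200/200 (0.64), while Eif2s3y (0.27, −0.18 and 0.43) and Uty (−0.14, 0.43 and −0.36) did not pass the fold size in any mutant. Ddx3y had log2 ratios of −0.60 in HDQ150/150, 0.60 in HDQ200/200 and −0.76 in HDQ315/+, so the Y-linked genes did not all move alike. After length correction the sex-linked list was uncalled in HDQ200/200 (median 0.28). Several genes of uncertain assignment were among the most extreme: Gm3893, in a repeated region, had 6.09, 0.799, 15.0 and 5.48 FPKM, and Peg3as, antisense to another gene on a strand that was not stated, 27.2, 18.2, 67.2 and 9.17 FPKM.

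For the choroid plexus genes, lower in all 3 mutant libraries, more choroid plexus tissue in the HDQ+/+ library was tested on 4 members too low for the list test, Aqp1, Slc4a5, Prlr and Tmem72. Their summed fragments were 1275 in HDQ+/+, 41 in HDQ150/150, 72 in HDQ200/200 and 144 in HDQ315/+, scaled count ratios of 0.0523 (0.0374 to 0.0714), 0.0647 (0.0503 to 0.0821) and 0.163 (0.137 to 0.194). These members belong to the list whose fall was seen, and a fall within the plexus would lower them alike, so more tissue and a change within the plexus cannot be told apart. A trend with transcript length was argued against, the median staying at −1.96 or lower in each library after length correction (percentile 0). Each genotype came from 1 library, so an effect of genotype stays open and untested.

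For the projection neuron genes, lower in all 3 mutant libraries, a trend with transcript length was argued against, the median of 43 genes of the 3 lists being −0.87, −0.70 and −0.46 after length correction (percentile 0 in each). A smaller share of striatal tissue in the mutant libraries was tested on the cholinergic interneuron genes Chat, Slc5a7, Slc18a3 and Lhx8, with medians of −0.58, −0.51 and −0.33 against −0.90, −0.78 and −0.46 for 44 projection neuron genes. The differences were 0.31, 0.27 and 0.13, with a mean of 0.238. A smaller striatal share would keep the difference within 0.3 in each library. HDQ200/200 and HDQ315/+ met this, and HDQ150/150 lay just over the bound. To count against it, each difference had to exceed both 0.3 and the SD of the cholinergic genes (0.14, 0.37 and 0.19), which only HDQ150/150 did. A smaller striatal share and a change within projection neurons therefore cannot be told apart, because only 4 cholinergic genes were measured and dissection is confounded with genotype, whose own effect stays open and untested. Some markers of neighbouring regions moved the other way, with cortical medians of 1.27, 0.81 and 0.33 and a thalamic median of 1.64 in HDQ315/+, but the thalamic median was −0.10 in HDQ150/150 and −0.00 in HDQ200/200.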
